A study of Rattus norvegicus with 8 samples.

How the data were processed

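Gene expression was measured in BRL-3A cells, an established line derived from rat liver, 48 h after lipofectamine transfection, per the labels. The labels give 2 groups of 4 arrays: cells transfected with an siRNA against the long noncoding RNA lnc19959.2, and cells whose transfection is labelled NC. Total RNA was labelled with Cy3 by a low input amplification kit and hybridised to Agilent Whole Rat Genome arrays, 1 sample per array, per the labels' protocols.

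The deposited scanner files hold the spot intensity of each array. Per the file headers, Agilent Feature Extraction 12.0.3.1 was used (the submitters' processing notes give version 12.0), and its processed intensity is background-subtracted and detrended within the array, with surrogate values near 0 and no scaling between arrays. The files also hold the mean pixel intensity of each spot and the median of its local background, per the file headers. A second table, the authors' deposited series table, holds log2 values of 86 probes on the same 8 arrays; limma is named in the submitters' processing notes, with no role given. All 86 probes matched a probe of the scanner files. Each column of that table was set against the same array's scanner values on the log2 scale, which gave correlations of 0.997 to 1.00, and its values lay within 0.01 of quantile-normalized log2 intensities at the median. The medians of its columns were 5.34, 5.18, 5.17 and 5.45 for NC replicates 1 to 4 and 5.53, 5.24, 5.32 and 5.72 for siRNA replicates 1 to 4. This left its scale (log2), its direction and the lack of centring settled by the comparison, while the authors' normalization method is not given in the sources used here. The table was used as an alternative only.

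Each array held 45018 spots, of which 43379 were not controls and represented 41012 probes. Control spots and spots that Feature Extraction had marked as non-uniform or population outliers (129 to 174 per array) were left out, and no spot was saturated. Processed intensities were taken to log2, the array's 75th percentile was subtracted, and spots of the same probe were averaged. Probes were kept if they were well above background, by the scanner software's own mark, on at least 3 of the 4 arrays of at least 1 group, which left 24853 probes. Names came from the accession in the scanner files through the RefSeq gene table of the GRCr8 assembly (18028 probes), from a file symbol that the table lists as current (3168) or older (400), or from the file alone (1288); 18128 probes stayed unnamed. The named probes covered 17542 genes. A gene was represented by its brightest kept probe over all 8 arrays. Of 3821 other kept probes of 3007 genes, 1766 were called together with the brightest one, 1575 in the same direction and 191 in the opposite direction. Probe positions are those of the array design on rn4.

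The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the kept probes and calls at an adjusted p under 0.05, and also with a size threshold of 2-fold. Fold changes are log2 differences, siRNA minus NC, with the standard error (SE) of the fit. For a probe well above background on no array of a group, the fold is a lower bound, as it is where named below for a gene above background on 1 array. The bright group's mean was set against the mean, per array of the dim group, of the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists were tested with limma's camera (preset correlation of 0.01, two-sided, adjusted over 22 lists), with camera at a correlation estimated from the data, and with fry, which asks whether the members move one way on balance and does not compare them with other genes. The set tests used 11466 of the 11476 measured genes.

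The groups, the tests, the 22 lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took Purb and Hnrnpa2b1 from the series title and 4 lipid genes recalled from the study (Apoa4, Cpt1a, Gpam and Tm7sf2). It also took the 10 highest and 10 lowest genes with a symbol among those past both thresholds on all 8 arrays, and up to 3 genes per direction with the largest bounds. In each list, up to 4 called members with the smallest adjusted p were named, of which 2 are not reported here. Since the 4 recalled genes came from the study, their direction is not independent evidence. Other members of a list that are named below were chosen after their values were seen. Nothing in the labels says that the arrays are separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

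The fit and the list test were run on simulated data of the same size as the comparison of siRNA with NC (24853 probes, 50 changed probes per size). The fit recovered 4% of changes of 0.25 on the log2 scale, 56% at 0.5, 78% at 1 and 92% at 2, and 1 of 116 calls was false. Only 200 simulated probes were changed, whereas 61.6% of probes were called in the real data. The adjusted p depends on that share, so these rates do not carry over to the real comparison. Simulated values were already scaled and filtered, so those steps were not tested. When a list of 35 genes was raised by 0.5, camera called that list and 0 of the 21 others. The simulated noise was drawn independently for each probe. In the real data the estimated correlation within the called lists ran from 0.095 to 0.937. False list calls from members that vary together were therefore not tested. Alternatives changed the scaling (quantile, median, cyclic loess, spike-in controls, percentile over probes bright on all arrays), the background correction (normexp, offset 50), the filter, the outlier spots, the variance model, array weights, the test, the probe representing a gene, the arrays entered and a replicate block. A normexp fit without spots dimmer than their local background was added after the data had been seen. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots.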

Results

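Expression of rat genes was profiled in 8 RNA samples from BRL-3A cells, a line derived from rat liver, 4 labelled NC and 4 transfected with an siRNA against the long noncoding RNA lnc19959.2. The 75th percentile of the processed spot intensity was 245 to 261 on the NC arrays and 289 to 322 on the siRNA arrays. A mean of 61.4% ± 3.03 (SD, n = 4) of spots lay well above background on NC arrays and 56.9% ± 1.63 (SD, n = 4) on siRNA arrays. The number of arrays limits the precision of every value. Across probes, the log2 signals of arrays correlated at r = 0.986 to 0.993 within a group and at 0.946 to 0.962 between groups, and no pair of arrays held identical values. All NC arrays were on 1 slide and in 1 scan and all siRNA arrays on another, so slide, scan and group cannot be told apart.

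The comparison of siRNA with NC addressed how the liver cells' transcripts, those of triglyceride metabolism in particular, differed after transfection with the lnc19959.2 siRNA. Interferon-response genes (28 of 36) and inflammatory genes (13 of 18) were lower in the siRNA cells, with Oasl 8.60-fold, Ifit3 11.2-fold and Ptgs2 4.82-fold lower. Genes of the cell cycle (32 of 35) and of the insulin-like growth factor system (8 of 10, with Igf1r lower) were higher, with Birc5 3.41-fold, Mki67 2.35-fold and Igf2 4.73-fold higher. None of these lists was called with an estimated correlation (adjusted p from 0.592 to 0.677), and the growth factor list also lost its call with median and spike-in scaling. Among lipid genes the apolipoproteins Apoa4, at least 42.7-fold lower, Apoa1, Apoa5 and Apoe fell and Apoc1 and Apoc3 rose, while Scd, Acaca and most other genes of fatty acid synthesis rose by less than 2-fold (n = 4 arrays per group; errors and tests follow).

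Of 11476 measured genes, 7412 differed between the groups by limma, 4053 higher and 3359 lower in siRNA cells. A difference of at least 2-fold was called for 467 higher and 1028 lower genes by fitted values. With genes above background on no array of the dimmer group counted by their lower bound, 417 higher and 839 lower genes reached 2-fold, and 53 higher and 212 lower genes reached 4-fold. At the level of probes, 7310 were higher and 8006 lower of 24853 tested, with 834 and 2431 at 2-fold or more. The split between higher and lower depended on the scaling. With median scaling 13020 probes were higher and 4211 lower (6866 and 1773 genes), and with scaling to spike-in controls 16249 were higher and 2729 lower (8256 and 1184 genes). At 2-fold or more, the higher and lower probes numbered 1281 and 1712 with quantile normalization, 1088 and 1956 with cyclic loess, 1935 and 1687 with median scaling and 3671 and 1316 with spike-in scaling. The corresponding genes numbered 642 and 816 with quantile normalization, 1053 and 759 with median scaling and 1947 and 621 with spike-in scaling. Median scaling moved the median of all probes by 0.31 on the log2 scale and spike-in scaling by 0.53, and each change below is relative to the 75th-percentile scaling.

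No probe carried the name of lnc19959.2, so the knockdown itself was not checked here, and no probe was named Purb, one of the proteins in the series title. Hnrnpa2b1, which encodes the other protein of the title, an RNA-binding protein of the hnRNP family, was 1.44-fold higher in siRNA cells (log2 fold change 0.53 ± 0.11 SE, adjusted p = 0.00313, n = 4 per group). Its probe lies on rn4 chromosome 4 from 79702868 to 79703012, and its other probe was also higher, by 0.35 ± 0.09 (SE). Apoa4, an apolipoprotein of triglyceride-rich particles (probe on chromosome 8, 49233335 to 49233394), was well above background on all 4 NC arrays and on 0 of 4 siRNA arrays. It was at least 42.7-fold lower in siRNA cells (adjusted p = 1.29e-06), with a mean log2 signal of 0.95 ± 0.18 (SD) in NC and -5.95 ± 0.59 (SD) in siRNA cells. Gpam, the acyltransferase of the first step of glycerolipid synthesis (chromosome 1, 261370372 to 261375755), was higher by 0.29 ± 0.05 (SE, adjusted p = 0.00247). Tm7sf2, a sterol reductase of cholesterol synthesis (chromosome 1, 208700867 to 208700926), was higher by 0.31 ± 0.07 (SE, adjusted p = 0.00426). Cpt1a, which controls fatty acid entry into mitochondria (chromosome 1, 205912066 to 205912125), did not pass the test (-0.10 ± 0.05 SE, adjusted p = 0.113), and its direction depended on the scaling. It was called higher with median scaling (0.22) and spike-in scaling (0.44) and lower with quantile normalization (-0.16), cyclic loess (-0.18) and the percentile over probes bright on all arrays (-0.16). Gpam and Tm7sf2 were both positive under every scaling tried. Rises of this size were not particular to them. Of 14 common reference genes, used as controls, 8 were also higher and 2 lower. Among the higher ones were Sdha (0.35 ± 0.05 SE) and Ppia (0.44 ± 0.06 SE). With normexp background correction Gpam stood at -0.01 and Tm7sf2 at 0.65 (adjusted p = 0.0865), and neither was called. With normexp without spots dimmer than their local background, both were called (0.18, adjusted p = 0.00431, and 0.38, adjusted p = 0.000243).

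**Figure D1:**
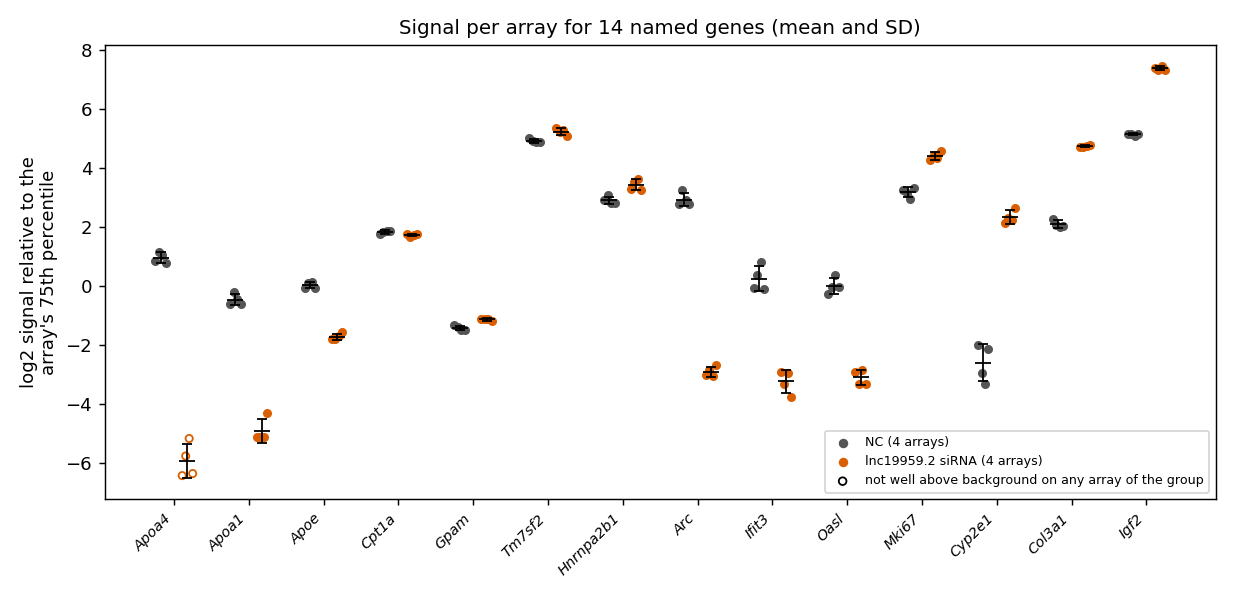
Log2 signal relative to the array's 75th percentile (vertical axis) for 14 genes named in the text (horizontal axis), with 4 NC arrays in grey and 4 lnc19959.2 siRNA arrays in orange; bars give the mean and SD, and open symbols mark a gene not well above background on any array of that group. Apoa4 lay at 0.95 in NC and at -5.95 in siRNA cells, while Cpt1a lay at 1.82 and 1.73.

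Apolipoprotein and lipoprotein genes went both ways, with 7 of 17 measured members higher, 8 lower and 2 not called (the same counts when adjusted over the list alone). Besides Apoa4, Apoa1, the main protein of high-density lipoprotein, was at least 15.5-fold lower (adjusted p = 2.61e-06) and above background on 1 of 4 siRNA arrays. Apoa5 changed by -1.91 ± 0.12 (SE) and Apoe by -1.75 ± 0.08 (SE), whereas Sort1, a sorting receptor, rose by 1.87 ± 0.14 (SE), Apoc3 by 0.78 ± 0.12 and Apoc1 by 0.44 ± 0.06. The list was not called by camera (adjusted p = 0.466). Its median of -0.11 turned positive with median scaling (0.20), spike-in scaling (0.42), quantile normalization (0.06) and cyclic loess (0.02).

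Fatty acid synthesis genes were mostly higher: 13 of 16 measured members rose, 2 fell and 1 was not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.592 with an estimated correlation). Scd, the desaturase that makes oleate, rose by 0.89 ± 0.11 (SE) at its brightest probe and by 0.15 ± 0.06 at its other one, Acaca, the carboxylase that makes malonyl-CoA, by 0.57 ± 0.07, Fasn by 0.44 ± 0.06 and the lipogenic regulator Srebf1 by 0.49 ± 0.05 (adjusted p of the brightest probes from 0.000165 to 0.000294). Fatty acid oxidation genes showed 18 of 27 members higher, 4 lower and 5 not called (18 and 5 adjusted over the list alone; camera adjusted p = 0.0176, and adjusted p = 0.592 with an estimated correlation). Hadh of mitochondrial oxidation rose by 1.19 ± 0.09 (SE) and Cpt2 by 0.60 ± 0.05, whereas Cpt1b fell by 1.84 ± 0.10 and the thioesterase Acot1 changed by -1.10 ± 0.10. Both lists lost their call with median scaling (adjusted p = 0.0730) and with spike-in scaling (adjusted p = 0.101 and 0.107), and fatty acid oxidation also with quantile normalization (adjusted p = 0.0620).

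Triglyceride synthesis and storage genes were not called as a list (adjusted p = 0.224), with 7 of 17 members higher, 3 lower and 7 not called, also when adjusted over the list alone. Agpat3 rose by 0.61 ± 0.07 (SE) and Mogat2 by 0.68 ± 0.05, while Mogat1 changed by -0.98 ± 0.08. Lpin2 rose by 0.41 ± 0.06 at its brightest probe, and its other probe gave -1.97. In lipolysis, with 3 of 10 members higher and 4 lower (the same adjusted over the list alone; adjusted p = 0.461), the monoacylglycerol lipase gene Mgll was 8.52-fold higher. G0s2, an inhibitor of triglyceride lipase, was 3.38-fold higher, and the lipoprotein lipase inhibitors Angptl4 and Angptl8 changed by -0.82 ± 0.09 and -1.11 ± 0.07 (SE). Of 11 genes of fatty acid uptake and activation 5 were higher and 4 lower (5 and 5 adjusted over the list alone; adjusted p = 0.891). Acsl3 rose by 0.59 ± 0.05 and Dbi by 0.68 ± 0.07, Cd36 was lower by at least 0.58 on the log2 scale with 3 of 4 NC arrays above background, and Slc27a4 (-0.38 ± 0.05) turned to 0.15 with spike-in scaling. In cholesterol synthesis 11 of 23 members were higher, 1 lower and 11 not called, also when adjusted over the list alone (adjusted p = 0.224). The list was called higher with normexp (adjusted p = 0.0117; 0.0858 without spots dimmer than their local background) and without a filter on dim probes (adjusted p = 0.0447). Dhcr7 was up by 0.68 ± 0.10 (SE), Sqle by 0.40 ± 0.07 and Ebp by 0.38 ± 0.07.

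Interferon-response genes fell together: 28 of 36 measured members were lower, 1 (Psmb9) was higher and 7 were not called, with the same counts adjusted over the list alone. Their median was -0.89 and lay below 0 under every scaling tried (camera adjusted p = 1.01e-06; adjusted p = 0.592 with an estimated correlation). Ifit3 changed by -3.48 ± 0.26 (SE), Oasl by -3.10 ± 0.17, Isg20 by -1.65 ± 0.09 and Ifih1, a sensor of double-stranded RNA, by -1.53 ± 0.09. Of 18 inflammatory and NF-kB target genes 13 were lower and 0 higher by limma, also when adjusted over the list alone, with a median of -1.27 (camera adjusted p = 0.00735; adjusted p = 0.677 with an estimated correlation). Ptgs2, which makes prostaglandins, changed by -2.27 ± 0.35 (SE), Ccl5 by -1.93 ± 0.28 and Birc3 by -1.91 ± 0.19. Il6 went from a mean log2 signal of -1.55 ± 0.59 (SD) to -3.55 ± 0.87 (SD), with 3 of 4 siRNA arrays above background. Beside these groups, Cd68, a macrophage marker, was 5.27-fold lower, and Cd14 was 0.20 ± 0.08 (SE, adjusted p = 0.0635), the remaining measured member of the leukocyte list.

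Cell cycle and DNA replication genes rose together, with 32 of 35 members higher, 0 lower and 3 not called by limma (32 and 1 adjusted over the list alone). Their median was 0.89 and positive under every scaling tried (camera adjusted p = 1.01e-06; adjusted p = 0.592 with an estimated correlation). Birc5 rose by 1.77 ± 0.16 (SE), the mitotic regulator Foxm1 by 1.27 ± 0.12, the proliferation marker Mki67 by 1.23 ± 0.10 and Ube2c by 1.05 ± 0.10. In the insulin-like growth factor system 8 of 10 members were higher and 1 (Igf1r) lower, also when adjusted over the list alone (camera adjusted p = 0.0170; adjusted p = 0.592 with an estimated correlation). Igf2 rose by 2.24 ± 0.05 (SE), Igf1 by 1.84 ± 0.11, and the binding proteins Igfbp2 and Igfbp4 by 1.61 ± 0.09 and 1.56 ± 0.10. The list's call was lost with median scaling (adjusted p = 0.0730) and spike-in scaling (adjusted p = 0.0873).

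Stress-response genes were lower in 2 lists. Of 18 p53 target and apoptosis genes 9 were lower and 4 higher (10 and 4 adjusted over the list alone; camera adjusted p = 0.0176; adjusted p = 0.592 with an estimated correlation), and their median of -0.45 stood at 0.08 with spike-in scaling. Plk2 changed by -2.51 ± 0.13 (SE), the antiproliferative gene Btg2 by -1.83 ± 0.10, Sesn2 by -1.11 ± 0.06, Mdm2, a negative regulator of p53, by -1.07 ± 0.06 and the cyclin-dependent kinase inhibitor Cdkn1a by -1.09 ± 0.07. Of 27 genes of the unfolded protein and integrated stress response 17 were lower and 1 (Ddit4) higher, also when adjusted over the list alone (camera adjusted p = 0.00235; adjusted p = 0.592 with an estimated correlation). Atf3 changed by -1.90 ± 0.19 (SE), Ppp1r15a by -1.72 ± 0.17 and Chac1 by -1.21 ± 0.07. The median of this list, -0.30, turned to 0.23 with spike-in scaling, where its call was lost (adjusted p = 0.0873), and to 0.01 with median scaling. Its call was also lost with normexp background correction (adjusted p = 0.350, 0 higher and 4 lower) but kept when spots dimmer than their local background were left out of it (2 higher and 17 lower). Its higher and lower members numbered 9 and 9 with median scaling and 16 and 5 with spike-in scaling. Oxidative stress and NRF2 target genes split into 5 higher and 7 lower of 17 (the same adjusted over the list alone; 7 and 3 with median scaling, 13 and 3 with spike-in scaling; adjusted p = 0.271), with Hmox1 at -1.37 ± 0.13 (SE), Srxn1 at -0.90 ± 0.12, Ephx1 at 1.64 ± 0.21 and Gclc at 0.68 ± 0.10. Glycolysis and hypoxia genes split into 8 higher, 8 lower and 8 not called, also when adjusted over the list alone (12 higher and 2 lower with median scaling, 16 and 1 with spike-in scaling; adjusted p = 0.821). Pdk1 was 0.79 ± 0.11 (SE), Tpi1 0.48 ± 0.07, Hk1 0.41 ± 0.05 and Adm -0.83 ± 0.12.

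Of 15 measured genes for hnRNP and Pur proteins 11 were higher, 0 lower and 4 not called by limma, also when adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.592 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.295), cyclic loess (adjusted p = 0.124) and spike-in scaling (adjusted p = 0.0548). Hnrnpr rose by 0.75 ± 0.07 (SE), Hnrnpab by 0.48 ± 0.06 and Hnrnpl by 0.46 ± 0.05. Hnrnpd was 0.60 ± 0.07 at its brightest probe and 0.07 at its other one (adjusted p = 0.464), and it stood at -0.01 with quantile normalization, where the other probe was the brighter one.

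Markers of other cell types went both ways and no list of them was called by camera (adjusted p from 0.476 to 0.821). Only part of each list had a kept probe: 8 of 25 hepatocyte, 16 of 21 fibroblast, 6 of 10 endothelial, 3 of 8 cholangiocyte and 2 of 13 leukocyte markers. Of the 8 measured hepatocyte markers 3 were higher and 3 lower, also when adjusted over the list alone. The cytochrome P450 gene Cyp2e1 was 30.7-fold higher and Foxa2 0.63 ± 0.11 (SE) higher. Krt18 was at least 6.39-fold lower with 1 of 4 siRNA arrays above background, and G6pc1 changed by -1.13 ± 0.12. Of 16 fibroblast and stellate cell markers 6 were higher and 4 lower (the same adjusted over the list alone), with the collagen genes Col3a1 up by 2.66 ± 0.07, Col5a1 by 0.83 ± 0.07 and Col1a2 by 0.61 ± 0.05. Among 6 endothelial markers 3 were higher and 3 lower, also when adjusted over the list alone: Kdr rose by 1.64 ± 0.19 and Eng by 0.89 ± 0.14, whereas Vwf was at least 8.18-fold and Tek at least 2.93-fold lower. Of the 3 cholangiocyte and epithelial markers Krt7 rose by 1.75 ± 0.11, while Spp1 changed by -0.46 ± 0.08 and Sox9, above background on 3 NC arrays and 1 siRNA array, was at least 1.66-fold lower (1 higher and 2 lower, also when adjusted over the list alone). Spp1 stood at 0.08 with spike-in scaling, and Sox9 kept its call in 10 of 18 alternative settings. Of the 2 leukocyte markers 0 were higher and 1 lower by limma (1 and 1 adjusted over the list alone). Common reference genes, used as controls, had 8 of 14 members higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.128), among them Gusb at 1.17 ± 0.07 (SE), Ppia at 0.44 ± 0.06, Sdha at 0.35 ± 0.05 and Tbp at 0.23 ± 0.04, each positive under every scaling tried. This control list was called higher with normexp (adjusted p = 0.00784), with normexp without spots dimmer than their local background (adjusted p = 0.0434) and without a filter on dim probes (adjusted p = 0.0291), which limits the reading of the other list calls there.

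**Figure D2:**
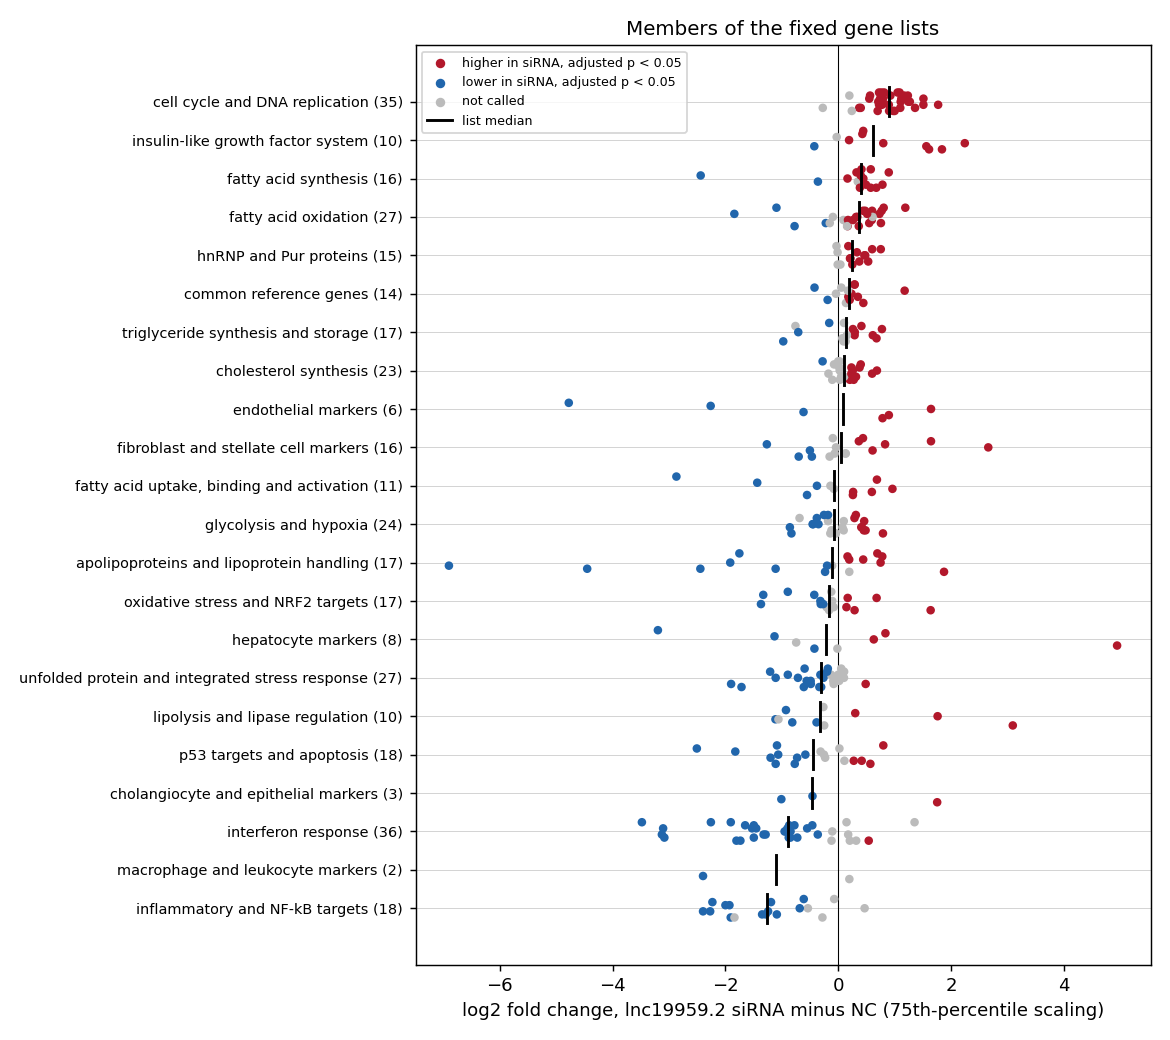
Log2 fold change, siRNA minus NC (horizontal axis), of each measured member of the 22 lists (vertical axis, with the number of members), coloured by whether limma called it higher, lower or neither at an adjusted p under 0.05; black bars mark list medians. Cell cycle genes centred on 0.89 and interferon-response genes on -0.89.

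Among genes measured on all 8 arrays, the highest besides Cyp2e1 and Mgll were Fmod, which encodes a collagen-binding proteoglycan (10.5-fold), the cadherin gene Cdh11 (10.4-fold), Pnoc (9.73-fold), Itm2a (7.33-fold), Pkhd1l1 (6.92-fold), Enpp2, which encodes autotaxin (6.32-fold), Col3a1 (6.30-fold) and Megf6 (6.11-fold). The lowest were Arc, an activity-induced early gene (57.3-fold lower), Ankrd34b (45.5-fold), Fam184b (26.1-fold), Apol7b (22.2-fold), Garin4 (18.1-fold), the AMP deaminase gene Ampd1 (17.5-fold), Marcksl1 (14.3-fold), Ifit3, Gpr15lg (10.9-fold) and Ctrb1 (9.87-fold). Standard errors of these log2 fold changes ran from 0.06 to 0.30 and the adjusted p from 3.95e-08 to 5.57e-05 (n = 4 per group). Klf14 was at least 53.8-fold and Slc9a2 at least 32.0-fold lower in siRNA cells, with no siRNA array above background. Wnt2b was at least 11.8-fold and Lgi4 at least 5.76-fold higher, with no NC array above background. The brightest Angpt2 probe was at least 4.79-fold higher and a second one at least 1.09-fold higher, while the third, above background on 3 NC arrays and no siRNA array, was at least 1.16-fold lower. Of the 1028 genes at least 2-fold lower, 448 (43.6%) were above background on no siRNA array at that probe, against 71 (15.2%) of the 467 higher genes on no NC array.

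In limma's camera with the preset correlation 9 of the 22 lists were called, 5 higher and 4 lower. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05 (smallest p = 0.0731), while fry called 20. The split of several lists followed the scaling. With spike-in scaling the higher and lower members numbered 14 and 1 for triglyceride synthesis, 23 and 0 for cholesterol synthesis, 8 and 2 for fatty acid uptake and 11 and 6 for apolipoproteins. They numbered 11 and 1 for fibroblast markers, 7 and 7 for p53 targets, 8 and 22 for the interferon response and 2 and 5 for NF-kB targets. The signs of test and values differed for some lists not called: fatty acid uptake had a median of -0.08 and fry pointed up, lipolysis had a median of -0.33 and a mean of 0.03, and the cholangiocyte list had a median of -0.46 and a mean of 0.09.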

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

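The tests of scaling, leukocytes, slide and detection limits below were chosen after the results had been seen; the test of gene order among lower genes and the counts over other splits of the arrays were not.

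Interferon-response and inflammatory genes were lower in the siRNA cells. Scaling between arrays is argued against as the whole cause: over quantile normalization, cyclic loess and the background corrections, the highest list median was -0.71 relative to the median of all genes. Scalings that shift all probes alike cannot move that value; under them the list medians themselves stayed below 0, the interferon list at -0.36 with spike-in scaling. Leukocytes in the NC cultures are argued against only as far as the leukocyte list goes. Of its 13 genes, 2 (Cd68 and Cd14) were above background on at least 3 NC arrays. Leukocyte genes outside the list were not counted and RNA of other foreign cells was not tested, so this count does not exclude either. Slide and scan cannot be told apart from the groups, because 0 of the 2 scans held both; a lasting effect of the lnc19959.2 siRNA and a response of the NC cells to their own transfection both stay open as hypotheses, and no array of untransfected cells was analysed here.

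Cell cycle genes were higher in the siRNA cells. The lowest list median was 0.80 above the median of all genes over quantile normalization, cyclic loess and the background corrections, the settings able to move that value, which argues against scaling as the whole cause. Slide and scan cannot be told apart from the groups here either, with 0 scans holding both. The siRNA may have raised proliferation, or the NC cells may have been denser or more stressed at harvest; neither was tested.

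Many genes were above background on NC arrays alone. For 260 of the 448 genes (58.0%) the NC level lay over 1 log2 unit above the mean siRNA detection floor (-4.46, against -4.39 for NC). That floor is the lowest signal among probes well above background, and brighter probes can miss the mark. Klf14 read -4.25 on siRNA replicate 2, whose floor was -4.67. Negative controls also varied more on the siRNA arrays (SD 2.02 to 2.46) than on the NC arrays (SD 1.13 to 1.83). A lower sensitivity of the siRNA arrays is therefore argued against only for genes far above the floor. Of these, 76 lay over 2 log2 units above it, and the explanation stays open for the rest. Adjacent genes on the GRCr8 assembly were both at least 2-fold lower 96 times, against 81.0 times after shuffling (ratio 1.19, permutation p = 0.0399, 10000 shuffles). The test took all 956 such genes placed on the assembly, whether or not they were above background on siRNA arrays. It therefore does not single out the genes above background on NC arrays alone. The bound set in advance against neighbouring genes as a source of the pattern was a ratio under 1.2, and the ratio met it. It did so by less than the 0.10 SD of the shuffles, a margin that was not part of the bound set in advance. Judged with that margin, the test decides neither way. Slide and group are confounded for this pattern too.

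Other splits of the 8 arrays into 4 and 4 gave far fewer calls. Of 35 splits, 1, the real one, called as many probes (15316, highest other 2). The same held for probes at 2-fold (3265, highest other 2), genes (7412, highest other 2) and genes at 2-fold (1495, highest other 2). Every other split mixed the 2 groups, so the difference between them entered the spread and kept the calls low. The low counts of the other splits therefore do not measure what chance alone would give. The real split ranked highest of the 35, and 35 splits cannot show more than that. A chance difference between cultures stays open as well, as the arrays of a group may not be separate cultures. For the number of called lists 2 of 35 splits called as many (9, highest other 9). The other of these 2 splits moved only 1 NC array away from its group. It thus kept part of the group difference and does not measure chance either. These splits cannot decide whether chance gave the list calls, and chance cannot be excluded there.

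Single arrays stood apart from the other 3 of their group in 8 of 224 sets of values, where chance gives about 11.2. Of these 8 sets, 5 were on siRNA replicate 4. The sets share arrays, so the total does not test whether 1 array stands apart. The gap to the nearest array, as a share of the group's range, was 0.943 for Srebf1 and 0.916 for Chac1 on NC replicate 2 (lowest and highest). On siRNA replicate 3 it was 0.850 for Ankrd34b (highest). On siRNA replicate 4 it was 0.969 for Apoa1, 0.955 for Eng and 0.873 for Igfbp2 (each highest), and 0.893 for Gpr15lg and 0.835 for Adm (each lowest).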

How the results depend on the processing

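The normexp fit without spots dimmer than their local background was added after the data had been seen; the other alternatives were planned.

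With quantile normalization 1281 probes were at least 2-fold higher and Hnrnpd stood at -0.0145. With median scaling 13020 probes were higher and 4211 lower (1935 at least 2-fold higher), as were 6866 and 1773 genes (1053 at least 2-fold higher), and Cpt1a stood at 0.22, while Slc27a4, Spp1 and Sox9 lost their call. With E1A spike-in scaling 16249 probes were higher and 2729 lower, 4987 of them by 2-fold (3671 higher, 1316 lower). Of genes, 8256 were higher and 1184 lower, 2568 of them by 2-fold (1947 higher, 621 lower), and 4 lists were called; Cpt1a stood at 0.44, Slc27a4 at 0.15 and Spp1 at 0.0756. Median and spike-in scaling shift all probes by construction, and 1567 probe calls turned to the opposite call under spike-in scaling, 114 under median scaling and 9 under quantile normalization. No call of at least 2-fold changed sign under a scaling, but 232 of the 3265 did under normexp on all spots.

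With normexp on all spots 3629 probes were called (1935 higher, 1694 lower), 1107 by 2-fold (453 and 654), as were 2047 genes (1225 and 822), 691 by 2-fold (371 lower), with Gpam at -0.0120. Another 25 named genes kept their direction and lost their call. They were Adm, Angpt2, Cd36, Ebp, Eng, Ephx1, Fasn, G0s2, G6pc1, Gclc, Hk1, Hnrnpab, Lgi4, Lpin2, Mogat2, Ppia, Sdha, Slc27a4, Sox9, Spp1, Sqle, Tbp, Tek, Tm7sf2 and Wnt2b. These losses came from spots dimmer than their local background. That fit put the median of NC replicate 1 at 521, against 90.4 to 103 on the other arrays; that array had 10 spots dimmer than their local background. Without such spots it was 95.1, no named gene changed its call (Gpam 0.18), and 769 probes differed by 2-fold (295 higher, 474 lower), as did 468 genes (193 and 275). The offset of 50 compresses changes of dim probes.

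Without a filter on dim probes 5679 probes differed by 2-fold (4610 lower), as did 2257 genes (1677 lower). With probes above background on all 8 arrays these were 1419 (826 lower) and 759 (415 lower), since probes bright in 1 group alone were left out. Signal over background thus limits how far the lower genes can be counted. The treat test against 1.2-fold called 7930 probes (3381 higher, 4549 lower), a stricter test by construction.

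Of the lists, 9 were called, 0 with an estimated correlation and 20 by fry, which pointed up for fatty acid uptake (adjusted p = 0.0447) and the cholangiocyte markers (adjusted p = 0.00322), where camera pointed down; the cause was not tested. Interferon, NF-kB, cell cycle and p53 lists were called in 22 of 22 alternatives with the preset correlation. All 22 share that preset and so do not test it. With it other splits of the arrays called up to 9 lists, but those splits mixed the groups and do not measure chance. Another probe of Lpin2 gave a fitted value of -1.97 and another of Angpt2 one of -1.48. That Angpt2 probe was above background on no siRNA array, so its fall is known only as the lower bound given above. The cause was not tested for either gene, nor for the lists lost under other scalings.

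Leaving out each array in turn gave 13102 to 15082 probes, 2558 to 3316 by 2-fold, 6502 to 7236 genes, 1221 to 1514 by 2-fold and 9 lists. Among named genes, Hnrnpd lost its call without each siRNA array in turn (0.04 to 0.13), as under quantile normalization, because its other probe then became the brighter of 2 nearly equal ones. Sox9 lost it without siRNA replicate 1 (adjusted p = 0.0523) or 4 (adjusted p = 0.0565) and was not tested without NC replicate 1, 2 or 3, where it missed the filter. With the replicate number as a block 7097 probes were higher and 7895 lower, and no call of a named gene or list changed. Deviations of same-numbered arrays correlated at -0.03 to 0.21, and those of arrays with different numbers at most at 0.09. Of the 8 arrays 2 correlated best with their own number, both of replicate 4 (0.21). Pairing by number was thus not seen for the other replicates, and the cause of the value for replicate 4 was not tested. In the authors' series table, kept probes numbered 59 and gave 33 calls against 33 from the scanner values, 26 in common and in the same direction and 0 opposite. Not run were the slide as a block, which could not be fitted, and the ordinary statistic, treat and the series table for lists.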

Other observations

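All tests in this part were chosen after the result had been seen, and the lists were written after some of their members had been seen.

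Immediate-early genes, transcribed within minutes of growth or stress signals, were lower in the siRNA cells. Of 32 measured members 28 were lower, 2 (Srf and Fosb) higher and 2 not called by limma. Fos changed by -3.18 ± 0.12 (SE), Egr1 by -3.00 ± 0.11, Nr4a2 by -2.44 ± 0.10, Klf6 by -1.86 ± 0.14, Myc by -1.82 ± 0.20 and Jun by -1.05 ± 0.10 (n = 4 per group). Since Arc, Fos, Egr1, Egr2 and Nr4a2 prompted the list, it was tested without them: 23 of the other 27 members were lower and 2 higher, with camera p = 2.29e-07 at the preset correlation and p = 0.0810 with an estimated correlation. The full list had given 8.27e-10 and 0.0668, and the members were left out only after that. That these genes fell as a group is therefore a hypothesis the data leave open, and it is confounded with slide as every group is.

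Imprinted genes were listed because Igf2 (2.24 ± 0.05 SE) and Dcn (1.64 ± 0.31) were among the higher genes. Of 17 measured members 10 were higher and 2 lower, with Cdkn1c at 1.56 ± 0.08 (SE), Grb10 at 0.93 ± 0.08 and Impact at -1.08 ± 0.08. The full list gave camera p = 0.0219, and p = 0.0485 with an estimated correlation (0.0668 adjusted over the 2 added lists), but these tests include the members that prompted it. Without Igf2, Igf2r, Cdkn1c and Dcn, left out only after that, 6 of 13 members were higher and 2 lower and p was 0.258 (0.276 with an estimated correlation), so a rise of imprinted genes as a group was not found.

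Genes at least 2-fold higher lay next to each other more often than after shuffling. Of 10394 adjacent pairs of measured genes on the GRCr8 assembly, leaving out pairs with a shared start of the symbol, 39 were both higher, against 17.8 expected (ratio 2.19, permutation p = 0.0001, the smallest that 10000 shuffles can give). Pairs included Dcn (1.64) with Epyc (at least 3.51-fold), Tk1 (1.10) with Birc5 (1.77), Top2a (1.51) with Igfbp4 (1.56) and Lgi4 (at least 5.76-fold) with Fxyd3 (2.24), as log2 fold changes except for the bounds. Shared regulation of neighbouring genes is a candidate explanation for the excess, and gene families without a shared symbol were not removed.

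Median log2 fold changes over the genes of each chromosome lay between -0.04 (chromosome 13) and 0.10 (chromosome 7). Such medians do not show where the called genes lie, and calls were not counted per chromosome.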
